A study of Homo sapiens with 4 samples.

How the data were processed

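DNA from HaCaT keratinocytes was enriched with an Agilent SureSelect capture kit, bisulfite converted and sequenced per the labels, in 1 library for each of 4 groups: Control, SFN, UA and UVB. The deposited table gives, per region and library, counts of CpG calls and counts of methylated CpG calls, made by the authors and not normalised further. For each region it also gives the number of CpGs and the annotation, assigned gene and distance to the gene start that the authors deposited. Bismark, Picard and ChIPseeker are named per the submitters' processing notes, without version or role. The values show regions of 4 to 500 bp with 3 to 89 CpGs (median 9 CpGs and 251 bp) and a blank wherever a library had under 20 calls. The genome build is not given in the sources used here. Of 22326 genes found under the same symbol and chromosome in GRCh38, 13.2% overlapped their GRCh38 position, so the printed positions are those of the table and not GRCh38. The GRCh38 gene table served for gene names and biotypes alone: of 24981 symbols, 22398 matched directly and 1553 as a synonym.

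The methylation level of a region is its methylated calls as a percent of its calls, and a difference is in percentage points. Calls at several CpGs of 1 read are counted separately, and reads carried no molecular identifiers in the sources used here, so intervals cover counting error and are too narrow for regions with many CpGs. Between treated libraries the variance over counting error was 1.42, 1.42 and 1.41, and in regions with 3 or 4 CpGs 1.00, 1.00 and 1.01. Averaged over the 3 pairs it rose to 2.29 in regions with 20 to 39 CpGs and 3.65 with more. Total calls were 134016940 to 177576747 per library, and the median calls per region were 274 in Control, 272 in SFN, 341 in UA and 255 in UVB. Assigned genes are the nearest by the table's annotation, and some collect large regions of the genome: 1456 regions carry the name HLA-DRB5 and 812 GPX6.

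The groups, comparisons, tests, gene lists, rule for named genes and the alternatives named below, except those marked as added, were chosen before the data were examined. Regions with at least 20 calls in all 4 libraries were tested with a two-sided Fisher's exact test on methylated and unmethylated calls for each of the 6 pairs of libraries, adjusted by Benjamini-Hochberg over the 315701 regions of each pair. A region was called gained or lost at an adjusted p under 0.05 and a difference of at least 20 points. Differences have Newcombe 95% intervals, pooled levels exact (Clopper-Pearson) intervals and plotted levels Wilson intervals. Promoter regions are those the table annotates as promoter, within 3 kb of a gene start. For each comparison with Control, 1 promoter region per gene was ranked by the interval bound nearest 0, and the 10 gains and 10 losses with the largest bounds were named, with non-coding and uncharacterised loci passed over. Also named were 3 gains and 3 losses outside promoters by the same rank, and up to 4 genes of each list with the largest difference in a called promoter region. Genes of multicopy families are named as uncertain. Members of counts of 5 or fewer, genes that differed between treated libraries and genes with many called regions were named after their values were seen. Some genes that these rules reach are not reported.

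The 20 gene lists were NRF2 target and antioxidant, epidermal differentiation, basal keratinocyte and hemidesmosome, p53 target, nucleotide excision repair, inflammatory cytokine and NF-kB, matrix metalloproteinase and matrix, carcinoma methylation, WNT and TGF-beta, chromatin enzyme, glycolysis and citrate cycle, methionine and one-carbon cycle, HOX, imprinted, protocadherin, cancer-testis, melanocyte, dermal fibroblast, immune cell and housekeeping genes. Beside the counts of called promoter regions, the median over genes of the pooled promoter difference was placed among 10000 random gene lists of the same size, matched by deciles of mean promoter methylation. The shared control was addressed with 20 simulations in which all 4 libraries were drawn at their pooled level, with the same numbers of calls. It was also addressed by splitting the Control calls at random into separate, equal shares. Coverage ratios were taken per 20 Mb bin from total calls, scaled to the library and adjusted for CpG density.

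Alternatives were a coverage minimum of 50, or of 20 in the compared libraries alone, difference thresholds of 10 and 30 points, an adjusted p under 0.001, counts divided by the number of CpGs, counts thinned to the lowest coverage, subtraction of the median difference, autosomes alone, the 1% of regions with the highest coverage left out, regions with at least 5 CpGs, promoters within 1 kb, and equal weights for regions. A coverage minimum of 10 was planned but is void, because counts under 20 are blank. Added after the data were seen were the other 2 treated libraries pooled in place of Control and bins of neutral coverage alone. The test was checked on simulated data in which 200 of 315701 regions were changed: at 25 points 74.6% were recovered for UVB, 85.1% for SFN and 76.1% for UA, at 40 points 89.4%, 95.5% and 90.9%, and at 15 points, under the threshold, 1.49%, 2.99% and 5.97%, with at most 2 false calls. The simulated calls were independent of one another, so this check left out CpGs counted several times on 1 read. Among 200 random lists of 30 genes, 8% lay outside percentiles 2.5 to 97.5 unchanged and 100% when moved by -5 points. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9.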

Results

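DNA methylation was measured in HaCaT cells, an immortalised line of human skin keratinocytes, by capture of part of the genome and bisulfite sequencing, which reads unmethylated cytosines as thymine. The labels describe 4 groups with 1 library each: a control given 0.1% DMSO, cells given SFN (sulforaphane, an isothiocyanate that activates the antioxidant regulator NRF2), cells given UA (a name that the labels do not expand), and cells exposed to 10 mJ/cm^2 of UVB (mg/cm^2 in another label) 10 times, about 1 week apart. SFN and UA were given to cells without UVB per the labels, and no library with both UVB and SFN was analysed here. There were no replicates, so Fisher's exact test compared libraries, not conditions, and intervals cover counting error only. The deposited table held 355538 regions of at most 500 bp with 3 to 89 CpGs. Total CpG calls were 143765822 in the Control library, 140445471 in SFN, 177576747 in UA and 134016940 in UVB, and the median calls per CpG were 28.3, 28.3, 35.5 and 26.6. All comparisons used the 315701 regions (88.8%) with at least 20 calls in all 4 libraries, of which 107705 were promoter regions of 23032 genes.

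The Control library had the highest methylation in every annotation class. Its pooled level, the methylated share of all calls, was 48.37% (exact 95% interval 48.36 to 48.38), against 46.72% in SFN, 46.71% in UA and 46.43% in UVB. Promoter regions stood at 29.7% in Control, 28.5% in SFN, 28.3% in UA and 28.0% in UVB, and distal intergenic regions at 52.6%, 50%, 50.3% and 50.2%. Introns stood at 69.7% in Control and 67.6% in UVB, and exons at 79.0% and 77.1%. The UVB difference from Control was -3.31 points over regions with 20 to 80% methylation in Control, -2.09 points over regions above 80% and -0.143 points over regions under 20%, classes set by the Control level itself. Weighting regions equally gave higher levels in every library, 58.6% in Control and 56.4% in UVB over all regions, with Control the highest except over regions under 20%, at 6.01% in Control, 6.46% in UVB, 6.45% in SFN and 6.54% in UA.

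**Figure D1:**
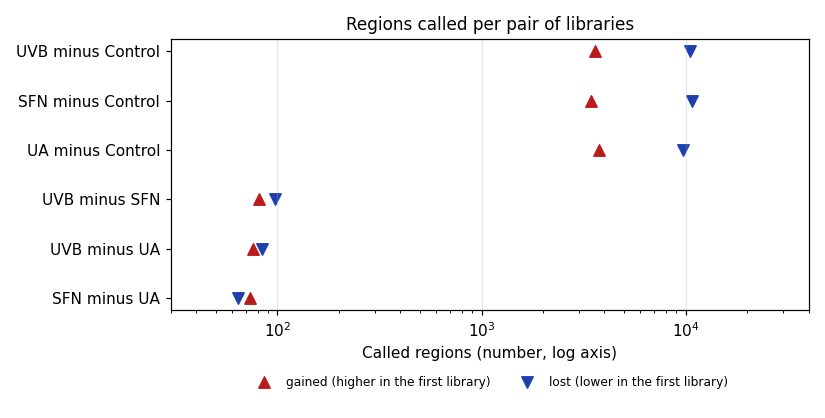
The number of called regions (log axis) for each pair of libraries; upward triangles are regions higher in the first-named library and downward triangles regions lower in it. The 3 comparisons with Control lie between 3436 and 10802 regions, and the 3 comparisons between treated libraries between 64 and 97.

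The first comparison asked which regions differed after repeated UVB. Unless said otherwise, a level beside a gene name is that of a single region, not of the gene or its whole promoter. The largest promoter gains lay in a zinc finger gene, a chaperone regulator, neuronal genes and an oxygen sensor. ZNF583 (chromosome 19, 56916664 to 56916758, 1281 bp inside the gene) rose from 7.69% in Control to 66.4% in UVB, a difference of 58.7 points (95% Newcombe interval 51.5 to 65.0, exact adjusted p = 3.05e-53). BAG2, a co-chaperone of HSP70 (chromosome 6, 57038175 to 57038258), rose from 34.1% to 81.5% (47.3 points, 43 to 51.4). CNTN4, a neuronal adhesion molecule, rose from 24% to 83.2%, and SCN1A, a voltage-gated sodium channel, from 36.4% to 80.7%. EGLN3, a prolyl hydroxylase that marks HIF for degradation, rose from 45.1% to 93.6%, and EDN2, an endothelin, from 38.9% to 88.5%. SHISAL2B, MS4A6A, ANOS1 and SLITRK2 completed the 10 largest gains, with UVB levels of 69.9%, 53.5%, 92.9% and 58.4%.

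The largest promoter losses took nearly all methylation from several regions. ITGB1BP2, which encodes the integrin-binding protein melusin (chromosome X, 70522805 to 70522866), fell from 85.7% to 3.28% (-82.4 points, -89.7 to -68.5). HOXC12 (chromosome 12, 54349961 to 54350294) fell from 73.4% to 3.8% (-69.6 points, -73.2 to -65.5, exact adjusted p = 1.64e-164). RUNX1, a transcription factor active in keratinocytes and blood (chromosome 21, 36421434 to 36421503, 92 bp inside the gene), fell from 80.2% to 15.1% (-65.1 points, -71.3 to -57.3). PRMT6, a histone arginine methyltransferase, fell from 67.2% to 3.81%, the scaffold protein gene FRMD4B from 75% to 15.4% and the phosphatase gene MTMR14 from 67.6% to 1.32%. MOB1B of the Hippo pathway fell from 96.0% to 34.9% and ITGB7, a leukocyte integrin, from 90.6% to 25.8%. APBB2 and ADCK5 fell to 9.07% and 23%. Outside promoters, an exon of the bicarbonate transporter gene SLC4A7 (chromosome 3, 27472829 to 27472959) rose from 13.2% to 92.6%, an intron of the pro-apoptotic gene BMF from 16.3% to 76.9%, and a distal region nearest NEBL from 6.00% to 69.4%. An intron of PC, in a region assigned to LRFN4, fell from 73.1% to 8.10%, a distal region nearest MFHAS1 from 82.2% to 18.3%, and an intronic region that the table assigns to the distant gene MAP3K14 from 70.9% to 5.05%. All 26 of these regions were also called, in the same direction, in SFN and in UA against Control.

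**Figure D2:**
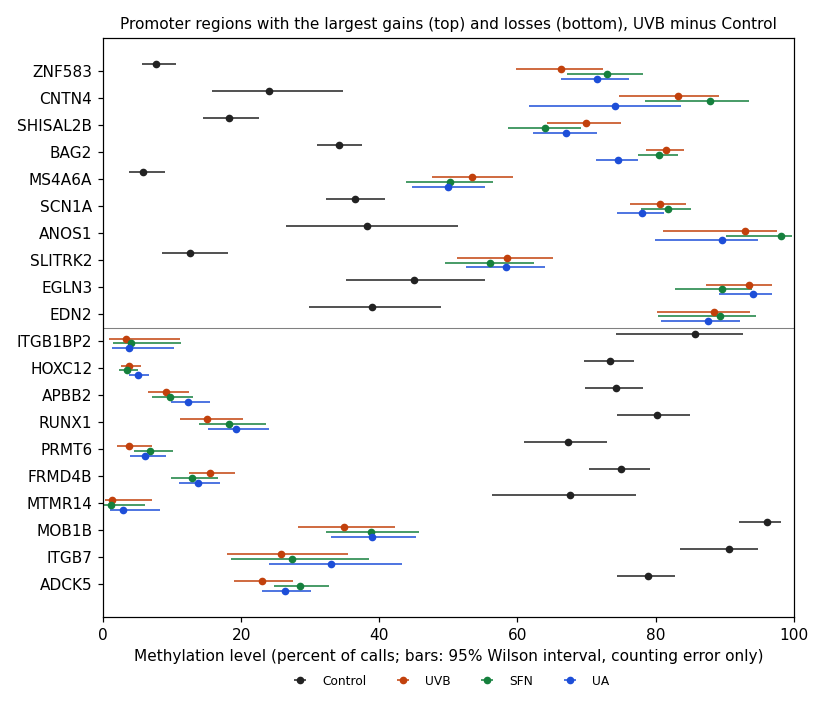
Methylation level (percent of calls, bars are 95% Wilson intervals for counting error) of the 10 promoter regions with the largest gains and the 10 with the largest losses in UVB minus Control, in each of the 4 libraries. ZNF583 stands at 7.69% in Control and between 66.4% and 73.0% in the other libraries, and HOXC12 at 73.4% in Control and between 3.47% and 5.01% in the others.

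In total 3585 regions gained and 10523 lost methylation in UVB relative to Control, 4.47% of those tested. Promoter regions accounted for 906 gains and 2984 losses, in 741 genes with gains alone, 2508 with losses alone and 108 with both. Called regions made up 6.07% of distal intergenic, 5.05% of intronic, 3.61% of promoter and 2.76% of exonic regions. With counts divided by the number of CpGs, 321 gains and 966 losses were called, and 33 of the 87 regions named by the fixed rule kept their call. This counts a read once only if it covers every CpG of the region, and it leaves fewer counts in each test. Against the pooled SFN and UA libraries in place of Control, an alternative added after the data were seen, UVB had 55 gains and 68 losses.

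Called regions made up 1.63% of the promoter regions of NRF2 target and antioxidant genes in UVB, 3.61% of those of epidermal differentiation genes and 2.72% of those of basal keratinocyte genes, against 3.61% of all promoter regions. The median promoter level in Control was 20.9%, 65.6% and 14.8% in these lists, and a region under 20% in Control cannot be called lost. Of 40 measured NRF2 target and antioxidant genes, 38 held no called region: 1 region gained and 3 lost, also 1 and 3 when adjusted over the list alone. AKR1B10, an aldo-keto reductase induced by NRF2, fell from 68.0% to 27.6% in 1 region and gained in another, and FTL, the light chain of ferritin, fell in 2 regions, from 45.7% to 7.38% in the one that changed most. All 4 of these regions were called the same way in the SFN and UA libraries. Of 42 epidermal differentiation genes, GRHL3, PRDM1 and TGM1 gained 4 regions and KLK7 and S100A7 lost 2, likewise 4 and 2 adjusted over the list alone. PRDM1, a repressor of cell-cycle genes in differentiating cells, rose from 23.2% to 56.3%, and the desquamation protease gene KLK7 fell from 53% to 19.4%. Of these 6 regions, 4 were called the same way in all 3 comparisons with Control. Of 23 basal keratinocyte and hemidesmosome genes, ITGB1 (57.1% to 12%), DLL1 (90.5% to 60.4%) and KRT15 (58.5% to 38.1%) lost 1 region each and BCL11B gained 1 (56.0% to 76.7%). The counts were 1 and 3 adjusted over the list alone, and 3 of the 4 regions were called in all 3 comparisons.

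DNA damage genes held 2 called promoter regions in UVB. Of 30 p53 target genes, TP53INP1 (70.1% to 42.0%) and BAX (75.4% to 44.0% over 25 UVB calls) each lost 1 region, while 1 loss passed when adjusted over the list alone. Neither region was called in all 3 comparisons. None of the 129 promoter regions of 31 nucleotide excision repair genes was called, nor was any when adjusted over the list alone. Of 34 inflammatory cytokine and NF-kB genes, the viral RNA sensor gene TLR3 (5.13% to 34.1%) and the chemokine gene CCL20 (64.9% to 87.3%) gained and S100A12 (77.3% to 54.9%) lost. These 2 gains and 1 loss also passed when adjusted over the list alone, and 2 of the 3 regions were called in all 3 comparisons.

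The called promoter regions of matrix and tumour-related genes were more often losses than gains, as over all promoter regions (906 gains and 2984 losses). Counted as genes, 1 matrix gene held gains alone, 1 losses alone and 1 both. In 24 matrix metalloproteinase and matrix genes, 2 regions gained and 4 lost, with the same counts adjusted over the list alone and 3 of the 6 called in all 3 comparisons. THBS1 fell from 49.8% to 5.49% and fibronectin, FN1, from 37.4% to 11.7% in the promoter regions that changed most, and the collagenase gene MMP13 rose from 9.87% to 32.1%. Over all annotations FN1 gained 9 of 28 regions and lost 2, and the 7 gained in all 3 comparisons stood at 59.0% in Control and 83.3% in UVB. In 38 genes methylated in skin and other carcinomas, 2 regions gained and 8 lost, also when adjusted over the list alone, and 4 of the 10 were called in all 3. The oestrogen receptor gene ESR1 fell from 78.8% to 35.8% in a region of 3 CpGs and the tumour suppressor APC from 88.0% to 59.2% in 1 of 6 promoter regions. In 39 WNT and TGF-beta pathway genes, 1 region gained and 11 lost, with equal counts adjusted over the list alone and 8 of the 12 called in all 3. INHBA, which encodes an activin subunit, fell from 54.0% to 9.11%, SMAD4 from 76.7% to 36.1% and WNT3 from 79.5% to 45.0%.

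The called promoter regions of chromatin and metabolic genes were also mostly losses. They made up 4% of the regions of chromatin enzyme genes, 3.04% for glycolysis and citrate cycle genes and 1.54% for methionine genes. Of all promoter regions 3.61% were called. In 40 DNA methylation and chromatin enzyme genes, 1 region gained and 8 lost, the same adjusted over the list alone, and 8 of the 9 were called in all 3. The histone demethylase gene KDM6B fell from 78.1% to 33.3%, TET3, an enzyme that oxidises methylcytosine, from 69.7% to 34.1%, and the demethylase gene KDM6A rose from 19.3% to 55.2%. In 38 glycolysis and citrate cycle genes, 7 regions lost and none gained, also adjusted over the list alone, and 5 of the 7 were called in all 3. PGAM1 fell from 74.1% to 28.9%, GAPDH from 71.1% to 34.7% and ENO2 from 85.4% to 50.6%. In 25 methionine and one-carbon cycle genes, MAT1A (60.8% to 28.0%) and AHCYL1 (33.3% to 11%) lost 1 region each, in all 3 comparisons and also adjusted over the list alone.

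Developmental, imprinted and lineage genes included losses over regions with many CpGs. In 38 HOX genes, 2 regions gained and 12 lost, also adjusted over the list alone, and 9 of the 14 were called in all 3. HOXC8 fell from 47.9% to 13.9% over 33 CpGs, and HOXD10 rose from 59.8% to 87.1%. In 26 imprinted genes, 2 regions gained and 6 lost, with 7 losses when adjusted over the list alone, and 7 of the 8 were called in all 3. DIRAS3, a maternally imprinted growth inhibitor, fell from 34.5% to 6.54% over 2248 UVB calls, and RB1 rose from 43.5% to 72.4%. In 38 protocadherin cluster genes 5 regions lost, in 24 cancer-testis germline genes 1 gained and 3 lost, and in 25 housekeeping genes 1 lost (GAPDH again), with the same counts adjusted over the list alone. The calls made in all 3 comparisons were 3 of 5, 2 of 4 and 1 of 1. BRDT, a testis bromodomain gene, fell from 80.8% to 30.6%, while values for protocadherin and MAGE genes are uncertain because their sequences resemble one another. Markers of other skin cell types lost regions too: OCA2 and SOX10 of 15 melanocyte markers, COL5A1, PRRX1 and PDGFRB of 19 dermal fibroblast markers, and 5 regions among 19 immune cell markers, among them CD14 (50.1% to 17.3%). LUM, a fibroblast proteoglycan gene, gained 1 region (33.0% to 53.1%). Adjusted over the list alone, the losses numbered 2, 4 and 5, and 1 of 2, 3 of 4 and 3 of 5 called regions were called in all 3 comparisons.

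The second comparison asked what SFN alone did to unexposed cells. The genes with the largest changes were mostly those named for UVB, joined by a sterol sensor, a cardiac gene and a tight junction gene. ZNF583 stood at 73.0%, CNTN4 at 87.8% and ANOS1 at 98.1% in SFN, against 7.69%, 24% and 38.2% in Control. SCAP, which escorts the sterol regulator SREBP, rose from 45.1% to 96.8%, the cardiac troponin gene TNNT2 from 14.9% to 59.7% and the transcription factor gene DMRT2 from 9.88% to 57.7%. CLDN4, a tight junction claudin (chromosome 7, 73245773 to 73246250), fell from 55.8% to 2.35% (-53.5 points, -56.3 to -50.4, exact adjusted p = 7.32e-194). HHATL fell from 69.2% to 5.71%, and ITGB1BP2, HOXC12, RUNX1 and MTMR14 reached 4.05%, 3.47%, 18.3% and 1.11%. Outside promoters, a distal region nearest RPTN, an epidermal matrix gene, rose from 6.35% to 67.5%, one nearest KCNIP4 from 21.7% to 84.7%, and the SLC4A7 exon reached 99.5%.

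In SFN 3436 regions gained and 10802 lost relative to Control (4.51%), including 900 and 3014 promoter regions in 758 genes with gains alone, 2549 with losses alone and 97 with both. CpG-scaled counts gave 386 gains and 1147 losses, and 38 of 92 regions named by the rule kept their call. Against the pooled UVB and UA libraries SFN had 63 gains and 47 losses.

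For the NRF2 list, the pathway that SFN activates, 4 regions gained and 5 lost, also adjusted over the list alone, and 33 of 40 genes held no call. Called regions made up 3.66% of the promoter regions of this list, close to the 3.63% of all promoter regions in SFN. Over the 20 lists the share in SFN ran from 0% to 6.25%. FTL fell to 5.84% and AKR1B10 to 26.6% in the regions named for UVB. GCLM, which encodes a subunit of the enzyme of glutathione synthesis, fell from 56.0% to 26.9%, and the transporter gene ABCC3 rose from 30.7% to 57.6%. SLC7A11 and TKT held the other gains outside AKR1B10, and SQSTM1 the other loss. In epidermal differentiation genes 2 regions gained and 6 lost, among them NOTCH3 (80.2% to 43.9%). In basal keratinocyte genes 4 regions lost, among them KRT15 (58.5% to 26.8%) and the hemidesmosome integrin gene ITGB4 (40% to 12.5%). No region was called in p53 target genes or in repair genes. In inflammatory genes 3 regions gained, CCL20, CXCL10 (30.2% to 60.2%) and TLR3 (to 38.7%), and 4 lost, among them TLR2 (36.1% to 10.7%). Matrix genes had 2 gains and 5 losses, with THBS1 at 2.23% and FN1 at 9.48%. Carcinoma genes had 1 gain, in CCND2 (0.939% to 28.1%), and 10 losses, and WNT and TGF-beta genes 2 gains and 14 losses, 5 of them in WNT3. All of these counts were equal when adjusted over the list alone.

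Chromatin enzyme genes had 1 gain and 9 losses in SFN, with KDM6B at 22.5% and the deacetylase gene HDAC7 falling from 91.8% to 47.9%. Glycolysis and citrate cycle genes had 8 losses, methionine cycle genes 3, among them PHGDH of serine synthesis (77.9% to 56.4%), and protocadherin genes 6. HOX genes had 2 gains and 10 losses, 11 when adjusted over the list alone, and imprinted genes 2 gains and 6 losses, among them PEG3 (87.7% to 63.2%). Cancer-testis genes had 1 gain and 3 losses, melanocyte markers 3 losses, fibroblast markers 2 gains and 4 losses, immune markers 4 losses and housekeeping genes 3 losses, in GAPDH and ACTB. COL3A1 fell from 57.3% to 25.9%, and ACTB from 88.3% to 62.9% in the region that changed most. Apart from the HOX losses, these counts did not differ when adjusted over the list alone.

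The third comparison asked the same of UA. It shared with UVB and SFN the losses in ITGB1BP2, HOXC12 and RUNX1 (3.70%, 5.01% and 19.2% in UA) and the gain in ZNF583 (71.5%). TAB2, an adaptor of NF-kB signalling, rose from 20% to 71.2%, the myosin gene MYO1G from 11.7% to 54.2%, and ADGRB3 from 9.52% over 21 Control calls to 70.4%. ALDH1A3, an enzyme of retinoic acid synthesis (chromosome 15, 101420808 to 101421166), fell from 76.5% to 23.9% (-52.6 points, -55.1 to -49.9), and AHDC1 from 94.3% to 32.8%. A distal region nearest TRAT1 rose from 6.67% to 69.1%.

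In UA 3747 regions gained and 9670 lost relative to Control (4.25%), including 934 and 2743 promoter regions in 775 genes with gains alone, 2329 with losses alone and 104 with both. CpG-scaled counts gave 519 gains and 1265 losses, and 42 of 90 regions named by the rule kept their call. Against the pooled UVB and SFN libraries UA had 55 gains and 46 losses.

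NRF2 target and antioxidant genes had 2 gains and 5 losses in UA, with FTL at 12.5%, TKT of the pentose phosphate pathway rising from 4.05% to 31.3% and GPX4, which detoxifies lipid peroxides, falling from 82.5% to 62.3%. Called regions made up 2.85% of the promoter regions of this list, against 3.41% of all promoter regions in UA. Over the 20 lists the share in UA ran from 0.581% to 6.25%. Epidermal differentiation genes had 3 gains and 7 losses: TGM1, which crosslinks the cornified envelope, rose from 41.9% over 31 Control calls to 85.9%. Basal genes had 3 losses, p53 targets 1 (TP53INP1, to 36%) and repair genes 1, in the ligase gene LIG3 (45.7% to 24.6%). Inflammatory genes had 3 gains, among them CXCL10 (to 64.9%), and 1 loss, in the inflammasome gene NLRP3 (72.2% to 49%). Matrix genes had 4 losses, with THBS1 at 0.971% and SPARC falling from 89.7% to 65.3%. Carcinoma genes had 1 gain and 5 losses, WNT and TGF-beta genes 1 and 9, chromatin enzyme genes 1 and 7, and glycolysis genes 1, in ACO1 (24.4% to 48.2%), and 6. Methionine genes had 2 losses, HOX genes 3 gains and 13 losses, protocadherin genes 2 and 5, cancer-testis genes 4 losses, melanocyte markers 4, among them PMEL (86.0% to 62.7%), and housekeeping genes 1. Imprinted genes had 2 gains and 9 losses, fibroblast markers 2 and 4, and immune markers 4 losses, with CD14 at 15.6% against 50.1% in Control. Adjusted over the list alone these last 3 lists had 10, 5 and 5 losses, and the other counts did not differ.

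The 3 treated libraries were set against one another because the design holds 1 control library for all of them. Regions called in all 3 comparisons and in the same direction numbered 1977 gains, 55.1% of those in UVB, and 6044 losses, 57.4%. UVB and SFN shared 2265 gains and 7335 losses, and 1 region was called in opposite directions. UVB and UA shared 2456 gains and 7058 losses, with 2 called in opposite directions. Over the 14108 regions called in UVB, the SFN level differed from Control in the other direction in 0.454% and the UA level in 0.354%. The median over regions of the ratio to the UVB difference was 0.922 for SFN and 0.910 for UA. These values share the Control calls that selected the regions. Selection by a large UVB difference can itself lower such ratios, here and in the next analysis. In an analysis added after the data were seen, with 1 random share of the Control calls for UVB and the other share for SFN and UA, UVB had 3347 gains and 9832 losses, of which 1594 and 5472 were also called in SFN and 1729 and 5198 in UA. Over these regions the SFN and UA levels each differed in the other direction in 2.31%, and the median ratios were 0.822 and 0.803. Unchanged libraries would differ equally often in both directions only if calls were independent. The shares were drawn from calls, so calls of the same read can fall in both and keep part of the Control error shared. Across all tested regions, which are not independent replicates, r between the UVB and SFN differences was 0.861, against 0.491 in simulated libraries that differed from Control by counting error alone, and 0.676 with a separate random share of the Control calls for each. For UVB and UA these values were 0.873, 0.517 and 0.682.

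Direct tests between treated libraries called few regions, and their genes were chosen after the values were seen. UVB and SFN differed in 81 gains and 97 losses, UVB and UA in 76 and 84, and SFN and UA in 73 and 64. GPX1, a selenium peroxidase of the NRF2 list (chromosome 3, 49394869 to 49395231), stood at 50% in UVB and 51% in UA but at 29.1% in SFN and 32.1% in Control (UVB minus SFN 20.9 points, 12.6 to 28.6, exact adjusted p = 0.00129). NOTCH3, a receptor of keratinocyte differentiation, stood at 66.0% in UVB, 43.9% in SFN and 80.2% in Control (22.1 points, 12 to 31.5, exact adjusted p = 0.00943). GRHL3, a transcription factor of barrier formation, stood at 38.3% in UVB, 17.8% in UA and 28.8% in Control (20.6 points, 14.3 to 26.5, exact adjusted p = 1.25e-06), and the germline gene PIWIL1 at 69.7%, 42.4% and 40%. Over all 20 lists these 4 genes held the called promoter regions between UVB and another treated library. HRH2, a histamine receptor gene, stood at 29.4% in UVB and at 2.25% in SFN, 3.45% in UA and 12.2% in Control, and GALNT13 at 32.2% in UVB, 63.1% in SFN, 77.4% in UA and 79.7% in Control. VWA1 stood at 46.9% in UA and 81.4% in SFN, and SHH at 46.5% in UA and 6.35% in SFN. These regions held 19 to 54 CpGs, where 1 read is counted several times and intervals are too narrow, with 153 UVB calls over 54 CpGs in HRH2, 152 over 53 in GALNT13, 119 over 41 in PIWIL1 and 63 SFN calls over 21 in SHH. No region was called between treated libraries with CpG-scaled counts, which also leave fewer counts to test.

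**Figure D3:**
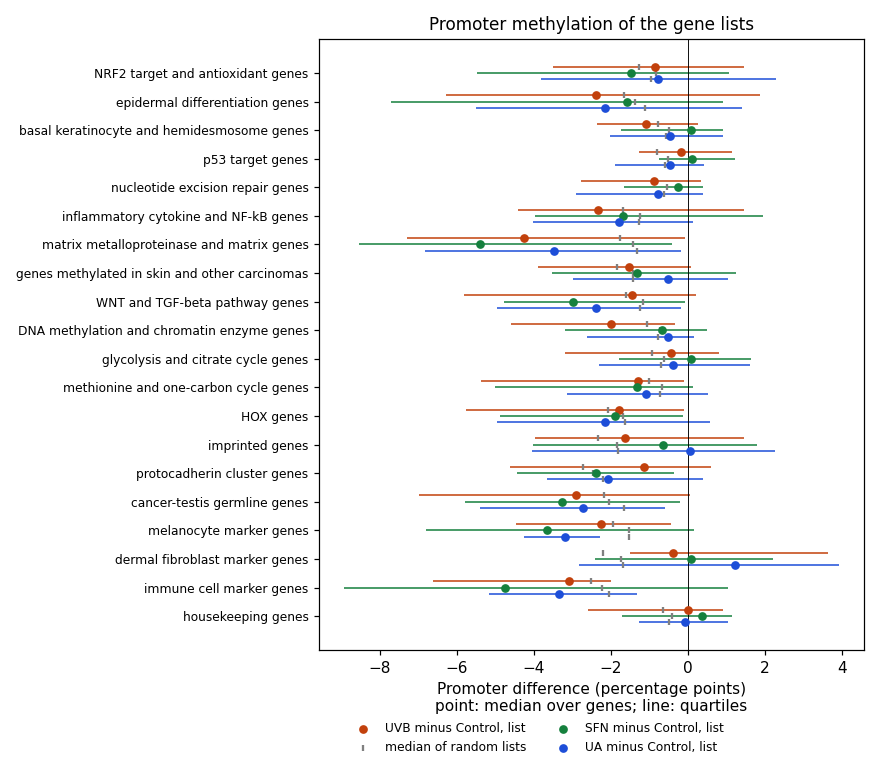
Difference in promoter methylation from Control (percentage points) of each gene list; points are medians over genes, lines run from the lower to the upper quartile, and grey ticks are the median of 10000 random lists matched on promoter methylation. Matrix genes lie at -4.25, -5.39 and -3.47 points in UVB, SFN and UA, and dermal fibroblast markers at 1.22 points in UA.

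Whole-list medians separated few lists from random genes. The median promoter difference of matrix genes was -4.25 points in UVB, -5.39 in SFN and -3.47 in UA, against -1.77, -1.44 and -1.32 in matched random lists, at percentiles 1.78, 0.07 and 2.36 of these. WNT and TGF-beta genes in SFN lay at percentile 1.37 (-2.97 against -1.16 points), fibroblast markers in UA at 99.3 (1.22 against -1.69) and housekeeping genes in SFN at 98.8 (0.379 against -0.401). All other lists lay between percentiles 5.40 and 97.2, including the NRF2 list at 77.9 in UVB, 14.3 in SFN and 63.2 in UA. Percentiles describe these libraries and carry no p. In a self-test 8% of unchanged random lists lay outside the outer 2.5% limits, so some lists can lie outside without any change. The comparisons also share 1 Control library. With promoter regions within 1 kb alone, matrix genes in UA moved to 6.94, WNT and TGF-beta genes in SFN to 28.0 and housekeeping genes in SFN to 32.2.

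Read coverage also separated Control from the other libraries. Over 159 bins of 20 Mb, the log2 ratio of coverage to Control, adjusted for CpG density, had an SD of 0.23 in UVB, 0.23 in SFN and 0.23 in UA, against 0.05 between UVB and SFN, 0.04 between UVB and UA and 0.02 between SFN and UA. On chromosome 1 the UVB ratio lay between 0.07 and 0.12 in each bin up to 140 Mb and between -0.60 and -0.45 from 140 to 220 Mb. On chromosome 6 it was 0.61 and 0.63 in the bins from 0 to 40 Mb, and between 0.04 and 0.07 beyond 100 Mb. Chromosomes 14 and 20 were raised throughout, by 0.38 to 0.45 and by 0.37 to 0.41, and chromosome 13 by 0.21 to 0.38. Chromosomes 5, 10, 16 and 18 were lowered throughout, at -0.36 to -0.09, -0.36 to -0.14, -0.30 to -0.15 and -0.42 to -0.07, and chromosomes 4, 8, 21 and X were raised throughout by at most 0.17. RUNX1 lay in a bin with a UVB ratio of 0.03 and ITGB1BP2 in a bin at 0.08, while ZNF583 and FTL lay in a bin at -0.34 and BAG2 in a bin at 0.24. In the 169062 regions of bins with all 3 ratios within 0.15 of 0, called regions made up 4.61% in UVB, 4.63% in SFN and 4.37% in UA, against 4.30%, 4.37% and 4.11% elsewhere.

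**Figure D4:**
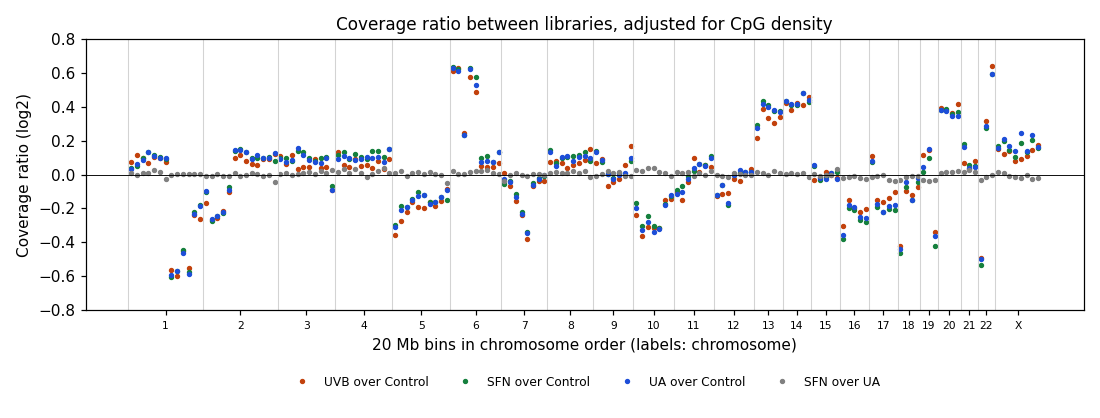
Log2 ratio of coverage between libraries in bins of 20 Mb, in chromosome order and adjusted for CpG density; coloured points are UVB, SFN and UA over Control and grey points SFN over UA. The ratios to Control step between -0.60 and 0.64 along chromosomes at the same places in all 3 libraries, while SFN over UA stays between -0.05 and 0.04; UVB over SFN and UVB over UA, not drawn, lay between -0.14 and 0.10 and between -0.15 and 0.08.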

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

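The alternatives with neutral coverage bins and with the other treated libraries pooled were chosen after seeing the data. Losses outnumbered gains against Control under every alternative run except when the other 2 treated libraries took the place of Control, where SFN and UA had more gains. Counts stayed within 1.5 times of those reported under a coverage minimum of 50 or in the compared libraries alone, thinned counts, subtraction of the median, autosomes alone and the top 1% of coverage left out. Gains and losses in UVB, SFN and UA were 11341 and 32199, 11342 and 33476, and 12821 and 31174 at a 10 point threshold, and 1089 and 3057, 1027 and 3153, and 1047 and 2696 at 30 points. With counts divided by the number of CpGs they were 321 and 966, 386 and 1147, and 519 and 1265. This setting leaves fewer counts in each test and also lessens the repeated counting of CpGs on the same read, and these effects were not told apart. With at least 5 CpGs they were 1876 and 6524, 1740 and 6632, and 1885 and 5844, and in neutral bins 2011 and 5788, 1933 and 5893, and 2119 and 5272. Fewer regions were tested in both, 246269 and 169062 of 315701. With at least 5 CpGs the counts fell by a larger share than the regions tested did. At an adjusted p under 0.001, UVB gains were 2338. Against the other 2 treated libraries pooled they were 55 and 68, 63 and 47, and 55 and 46, as a different reference was used.

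Calls between treated libraries (UVB and SFN, UVB and UA, SFN and UA) were 0, 0 and 0 with CpG-scaled counts, 108, 82 and 85 with thinned counts, 721, 689 and 665 at 10 points, 48, 51 and 39 at 30 points, 57, 45 and 53 at an adjusted p under 0.001, and 90, 85 and 81 in neutral bins. With equal weights, levels over all, promoter and distal intergenic regions were 58.6%, 43% and 54.7% in Control, 56.4%, 41.0% and 52.0% in SFN, 56.9%, 41.4% and 52.6% in UA, and 56.4%, 41.0% and 52.2% in UVB, because dense, poorly methylated regions weigh less. With separate random shares of the Control calls, the share of UVB-called regions that differed the other way was 0.758% in SFN and 0.766% in UA, and r was 0.676 and 0.682. These UVB-called regions were still selected with all Control calls. Where 1 share selected the regions and the other was compared, 2.31% differed the other way in SFN and in UA. Among list percentiles, 175 alternatives kept their side of the 2.5 and 97.5 limits. With promoters within 1 kb, epidermal differentiation genes in UA moved to 2.29, matrix genes in UA to 6.94, WNT and TGF-beta genes in SFN to 28.0, and housekeeping genes in SFN turned to the lower side at 32.2. Matrix genes in UA moved to 2.79 with a coverage minimum of 50; for these lists the cause was not tested. Of the regions named by rule, 79 of 87 in UVB, 88 of 92 in SFN and 82 of 90 in UA kept their call with thinned counts, 33, 38 and 42 with CpG-scaled counts, and 1, 0 and 0 against the other treated libraries pooled, the 1 being PIWIL1. No paired analysis was possible because each group had 1 library, and for the same reason no library was left out and no other splits of the samples were run. Depth limits the named regions most where a library had 20 to 50 calls, as for BAX, TGM1 and ADGRB3.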

Other observations

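Tests of bisulfite conversion, another stock, a shared response, CpGs on 1 read, exchanged labels and CpG density were chosen only after the result was seen, as were the genes of the next paragraph.

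Some genes changed in many of the regions assigned to them rather than in 1, and whether these regions adjoin was not tested. GRIK2, a kainate-type glutamate receptor gene on chromosome 6, had 20 of its 39 tested regions lost in UVB, SFN and UA alike, and the pooled level of these regions was 78.1% in Control and 46.4%, 46.2% and 46.5% in UVB, SFN and UA. XYLT1, an enzyme of proteoglycan synthesis, had 11 of 71 regions lost (67.0% in Control, 40.4% in UVB), ZIC2, a zinc finger gene of the forebrain, 8 of 23 (80.5% and 50.7%), and the tyrosine kinase gene FYN 8 of 43 (68.0% and 32.7%). In the other direction, TRMT9B, a tRNA methyltransferase-like gene on chromosome 8, had 18 of 49 regions gained in all 3 libraries (46.8% in Control, 81.5%, 81.6% and 81.7% in UVB, SFN and UA), and its neighbour DLC1, a tumour suppressor, 11 of 24 (34.0%, 69.3%, 72.3% and 70.5%). PTPRG, a receptor phosphatase gene, gained 14 of 45 (38.5% to 72.4% in UVB), CADM1, an adhesion gene often silenced in tumours, 9 of 82 (27.8% to 56.6%), and GAS7 8 of 35 (33.3% to 64.4%). HLA-DRB5 and GPX6 also ranked high, but these names collect regions across the MHC and adjoining parts of chromosome 6.

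The UVB, SFN and UA libraries shared most of their difference from Control. The tables argue against 3 technical causes: counting error of the shared Control library (r stayed at 0.676 with separate random shares of its calls), depth (at equal depth UVB minus Control calls were 123 times the largest count between treated libraries) and incomplete conversion in Control (at least 24.1% of calls were lower in Control). The call rate in neutral bins was at least 106% of that elsewhere, which argues against copy number differences that shift whole bins as the whole cause. Copy number differences within a bin, under the limit for neutral bins or without a change in coverage were not tested, because neutral bins were defined by their whole coverage. Control cells of another HaCaT stock or passage history are a candidate explanation: the coverage ratios to Control had at least 4.78 times the spread between treated libraries. A response shared by UVB, SFN and UA cannot be told apart from this for the methylation differences (at least 4.37% of regions called in neutral bins), because both predict the same values and each group had 1 library, but it would leave the coverage steps unaccounted for.

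The UVB library, by its label from cells grown through repeated exposures, lay close to SFN and UA, with few regions of its own. As labelled, UVB against pooled SFN and UA had 1.12 times the calls of SFN against the other libraries. The calls between UVB and SFN or UA may come in part from CpGs counted several times on 1 read: the ratio of call rates between regions with 20 or more CpGs and regions with 3 or 4 was at least 38.7 times that of UVB minus Control at an equal limit of p. An exchange of the Control and UVB labels cannot be told apart from Control cells of another stock: both predict a Control library apart from the others, and the variance over counting error of UVB with Control was 6.16 times that with SFN or UA. An exchange would turn the UVB minus Control differences around and leave SFN and UA with 178 and 160 called regions against the untreated cells in place of 14238 and 13417, and the exposed cells would differ from both by these larger counts, so repeated exposure as a source of regions specific to UVB cannot be told apart from the other explanations.

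Coverage of the treated libraries relative to Control stepped along chromosomes 1, 6 and 22, was raised by at least 0.21 (log2) over all of chromosomes 13, 14 and 20 and was lowered over all of chromosomes 5, 10, 16 and 18. The tables argue against CpG density, a proxy for GC content, as the cause: the spread over bins after adjustment was at least 99.8% of that before. Unequal copy number between the Control cells and the others is a candidate explanation that stays open, and no biological explanation from the design was tested for it.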
